A study of Homo sapiens with 3 samples.

How the data were processed

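Gene expression was measured in Panc-1, an established human pancreatic ductal carcinoma cell line, 48 h after treatment with 1 of 3 small interfering RNAs: a scrambled control (scr-siRNA), an siRNA against the transcription factor gene FOXO3 (FOXO3-siRNA) or an siRNA against PDHA1 (PDHA1-siRNA), the gene of the E1 alpha subunit of the pyruvate dehydrogenase complex. Total RNA of each culture was labelled with Cy3 and hybridised to 1 one-colour Agilent array, so the series holds 3 arrays, 1 per group, and nothing was pooled. The labels give no replicate cultures and no pairing. The file headers give 1 scan time for the series, so no batch could be set apart.

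Per the file headers, the scanner files hold linear fluorescence intensity values made by Agilent Feature Extraction, which had subtracted the background and corrected spatial trends within each array. The headers name version 10.7.1.1 of that software, whereas the deposited processing notes name 9.5.1.1. These deposited intensity values were not normalized between arrays. The deposited value table is another intensity table, which the authors had made quantile-normalized: its 3 columns share the same sorted values on a linear scale, and the sources used here do not state how it was made. The deposited scanner files also hold other columns, 0 or 1 flags that mark spots well above background, saturated spots and outlier spots per the file headers. No column of the deposited files was left unassigned (0 columns).

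Each array had 62976 features, of which 58717 were spots of 50599 probes for transcripts. Of these probes, 49697 were spotted once and 902 were spotted 10 times. No spot was saturated (0 on each array). Spots with an outlier flag were left out, which were 269 on the scr-siRNA array, 259 on the FOXO3-siRNA array and 436 on the PDHA1-siRNA array. Spots of 1 probe were averaged on the log2 scale. Each array was scaled by subtracting the log2 of its 75th percentile over the 22078 probes that were well above background on all 3 arrays, because fewer than 50% of all probes were well above background on any array. A probe counted as well above background when the flag was set for at least 50% of its spots.

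Probes were matched to gene symbols through their accessions (28170 probes), their symbols (2621) or older symbols (620) in a RefSeq gene table, and 19188 probes kept the name given in the files. The 50599 probes stood for 36400 names, 9536 of them with several probes. For these names the probe with the highest mean log2 value among those well above background on at least 1 array gave the gene's value. Chromosomes and probe positions are those of the deposited files, whose genome build is not given in the sources used here.

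With 1 array per group, no test was run and no p-value is given: the number of arrays limits the precision of every value. Log2 ratios were computed for FOXO3-siRNA against scr-siRNA, PDHA1-siRNA against scr-siRNA and FOXO3-siRNA against PDHA1-siRNA, over the genes well above background on both arrays of the comparison. A difference of at least 2-fold is a size rule and says nothing about significance. A gene well above background on only 1 of the arrays was given a bound, written as "at least". It was computed against the lowest signal well above background on the other array, or against the gene's own signal there where that was higher. That lowest signal was 16.6 on the scr-siRNA array, 16.9 on the FOXO3-siRNA array and 21.7 on the PDHA1-siRNA array. Where the gene's own signal was used, as for HORMAD1 and DIS3L, the bound is the plain ratio. A higher detection limit would give smaller folds, so these bounds are not guaranteed minimum folds. The repeated spots show scanner and spotting scatter alone: the median SD of a single-spot log2 ratio was 0.078 for FOXO3-siRNA against scr-siRNA, 0.087 for PDHA1-siRNA against scr-siRNA and 0.090 for FOXO3-siRNA against PDHA1-siRNA.

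The comparisons, the gene lists and the rule for naming genes were fixed before the data were examined. The named genes are FOXO3 and PDHA1, the 12 highest and 12 lowest log2 ratios of each comparison with scr-siRNA, and the 6 highest and 6 lowest of the direct comparison. They were taken among genes with a symbol, at least 2-fold different, with a mean level at or above the median of the genes measured. The rule also names the 5 genes highest and the 5 lowest in both knockdowns, up to 3 of the largest bounds in each direction, and up to 4 members of each list with the largest absolute log2 ratios. Some genes that the rule names are left out of the text.

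The 34 lists were FOXO factors, FOXO target genes, the pyruvate dehydrogenase complex and its regulators, glycolysis, the tricarboxylic acid (TCA) cycle, nuclear-coded oxidative phosphorylation subunits, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation, ATF4 amino acid response genes, endoplasmic reticulum chaperones, G1/S genes, G2/M genes, p53 targets, apoptosis regulators, autophagy and lysosome genes, NRF2 antioxidant genes, hypoxia genes, epithelial markers, mesenchymal markers, interferon response genes, NF-kB and inflammatory genes, stem cell markers, drug response genes, MYC targets, ribosomal proteins, replication histones, TGF-beta and SMAD targets, insulin and growth factor signalling, the siRNA machinery, housekeeping genes, leukocyte markers, endothelial and fibroblast markers, and pancreas and liver markers. They held 676 different symbols, 670 of them on the array. Each list's median log2 ratio was set beside 10000 random lists of the same size, each member drawn from the 200 measured genes nearest in mean level. The percentile among them, and the excess of the list's median over the median of the random lists, describe these arrays and are no test. Lists with fewer than 4 measured members were given values without a percentile.

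Both ratios against scr-siRNA use the same control array, which could not be split. Their Pearson r, covariance and overlap across genes were therefore set beside 100 simulations. Each simulation shuffled the 3 median-centred values of every gene among the arrays, so any knockdown differences stayed in the spread. Overlaps were also set beside the product of both counts over the number of genes.

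The alternatives fixed in advance were a normexp background correction (offset 50) on the raw spot and local background intensities, quantile normalization, median centring, the authors' value table, no filter on dim probes, a stricter brightness filter, the mean of a gene's probes, and leaving out every probe with a marked spot. The alternatives chosen after seeing the data were the 75th percentile over all probes, keeping the marked spots, leaving out array rows 1 to 200, and leaving out 2 streaks of low spots on the PDHA1-siRNA array. List percentiles under the alternatives used 2000 random lists.

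The calculation was tested on simulated data for each comparison, with 200 altered genes among the measured ones. The simulated noise was normal with the median SD of repeated spots. The measured log2 ratios varied more, with an SD of 0.350, 0.427 and 0.451 in the order in which the comparisons were given. Finding altered genes and shifted lists was therefore near certain, so the counts check the calculation and not the reliability of the measured differences. In the simulation of FOXO3-siRNA against scr-siRNA (17694 genes), 50 of 50 genes altered by 1.5 log2 units and 50 of 50 altered by 2.5 were found at 2-fold, and 0 of the unaltered genes were. In the same simulation, 100 of 100 lists of 15 genes shifted by 0.3 log2 units lay above the central 95% of random lists, against 3 of 100 unshifted lists outside it, and of unshifted lists of 25 genes 10 of 100 lay outside it. In the simulation of PDHA1-siRNA against scr-siRNA (16873 genes) these counts were 7 of 100 for lists of 15 and 5 of 100 for lists of 25, and in that of FOXO3-siRNA against PDHA1-siRNA (16787 genes) 8 and 3 of 100. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1 for normexp.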

Results

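Panc-1 cells treated for 48 h with scr-siRNA, FOXO3-siRNA or PDHA1-siRNA were profiled on 1 array each, 3 arrays in all. Of 50599 probes, 24631 (48.7%) were well above background on the scr-siRNA array, 24150 (47.7%) on the FOXO3-siRNA array and 23034 (45.5%) on the PDHA1-siRNA array. These stood for 18508, 18199 and 17507 genes, in the same order. The 75th percentile of the processed signal over the shared probes was 1769 on the scr-siRNA array, 1569 on the FOXO3-siRNA array and 1477 on the PDHA1-siRNA array. There were no replicates, so no difference below could be set against a replicate error.

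Each targeted transcript was lower on the array of its own siRNA than on both other arrays. FOXO3 codes for a forkhead transcription factor that acts in stress responses and is held in check by growth factor signalling. Its brightest probe, on chromosome 6 at 109005852 to 109005911, read a log2 level of 1.89 on the scr-siRNA array, 0.05 on the FOXO3-siRNA array and 1.80 on the PDHA1-siRNA array. The FOXO3 log2 ratio to scr-siRNA was -1.84 after FOXO3-siRNA, 3.58-fold lower with 28.0% of the control signal left, and -0.09 after PDHA1-siRNA. The other FOXO3 probes gave -1.80 and -1.65 after FOXO3-siRNA, and -0.068 and -0.13 after PDHA1-siRNA. On the PDHA1-siRNA array the spot of the brightest FOXO3 probe lay inside a streak of low spots described below. PDHA1 lies on chromosome X, and its probe at 19377888 to 19377947 read 2.48 on the scr-siRNA array, 2.54 on the FOXO3-siRNA array and -0.57 on the PDHA1-siRNA array. The PDHA1 log2 ratio was -3.05 after PDHA1-siRNA, 8.25-fold lower with 12.1% left, and 0.06 after FOXO3-siRNA. Averaging PDHA1 with its dimmer probe, which was well above background on the PDHA1-siRNA array alone, turned the ratio to 0.55.

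**Figure D1:**
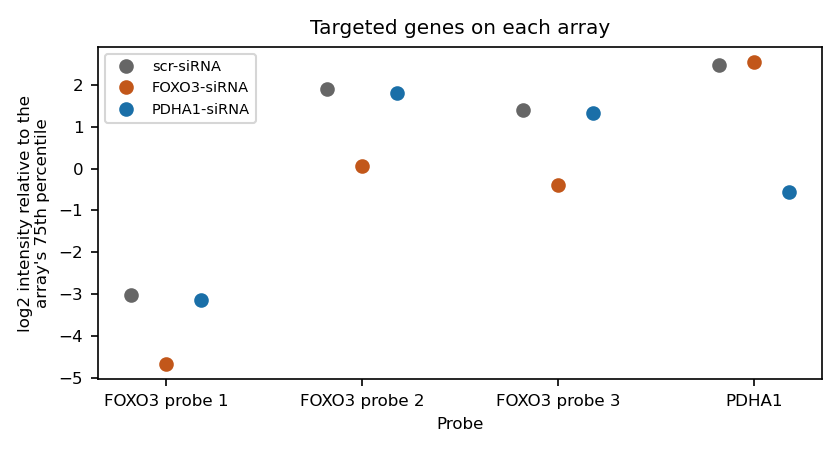
The log2 intensity relative to each array's 75th percentile is plotted for the probes of FOXO3 and PDHA1 that were well above background on all 3 arrays, 1 point per array. The FOXO3 probe used as the gene's value (probe 2) lay at 0.05 on the FOXO3-siRNA array against 1.89 on the scr-siRNA array, and PDHA1 lay at -0.57 on the PDHA1-siRNA array against 2.48.

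FOXO3-siRNA against scr-siRNA asked which transcripts differ when FOXO3 is silenced in these cells. EIF4EBP2, which codes for a repressor of cap-dependent translation, was 3.72-fold higher, and the interstitial collagenase gene MMP1 was 2.97-fold higher. At the other end, BZW1, a regulator of start codon choice, was 5.98-fold lower, and TENT5C, a poly(A) polymerase gene, was 6.41-fold lower. Inflammatory NF-kB genes such as CCL2 (log2 ratio 1.20) and BIRC3 (1.14) were higher, whereas amino acid response genes such as SLC7A11 (-1.14) and MTHFD2 (-1.06) were lower.

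Among 17694 genes well above background on both arrays, 150 were at least 2-fold higher and 223 at least 2-fold lower after FOXO3-siRNA. Next to EIF4EBP2 (log2 ratio 1.90, with 1.43 from its other probe) stood NIPA1 (1.83), the calcium-binding protein gene EFHD2 (1.78), MIGA1 (1.78), which acts in mitochondrial fusion, and the lysocardiolipin acyltransferase gene LCLAT1 (1.71). The heme synthesis gene CPOX (1.65), AKIRIN1 (1.60), the glycosyltransferase gene B3GNT5 (1.58), MMP1 (1.57, over 10 spots) and the translation factor gene EIF5A2 (2.83-fold) followed. The collagen gene COL1A1 was at 1.47 and the kinase gene MAP3K13 at 1.43, with 5 of its 6 other probes above 0 and 1 at -0.28. TENT5C (-2.68) and BZW1 (-2.58) were followed downward by PWP1 (-2.29), the phosphatase inhibitor gene PPP1R2 (-2.28), the mediator kinase gene CDK19 (-2.16) and the lysosomal sialidase gene NEU1 (-2.13). PCNP (-2.11), the prion protein gene PRNP (-1.99), the complex I subunit gene NDUFA8 (-1.94), TOMM34 (-1.87) and RAB31 (-1.87) were also among the 12 lowest. These rankings hold among genes with a symbol at or above the median level. Other probes gave the same direction for BZW1 (-2.58 and -1.41), PPP1R2 (-2.36 and -1.91) and TOMM34 (-1.87).

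A further 145 genes were well above background on the FOXO3-siRNA array and not well above background on the scr-siRNA array, with a bound of at least 2-fold, and 83 genes showed the reverse. By this bound, which is not a guaranteed minimum, HORMAD1 was at least 6.64-fold higher, KCNE1 at least 6.17-fold higher and SEMA5B at least 6.15-fold higher. For HORMAD1 it is the plain ratio to a scr-siRNA signal of 17.4 that was not well above background. The spots of HORMAD1 and SEMA5B lay in the last band of array rows, where 4.53% of the probes dim on both other arrays were well above background on the FOXO3-siRNA array, against 2.03% in rows 1 to 50. OR2T2 was at least 8.14-fold lower, the zinc finger repressor gene ZEB2 at least 7.11-fold lower and TNFAIP6 at least 6.31-fold lower.

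The NF-kB and inflammatory genes stood furthest from random lists matched on level. Their median log2 ratio was 0.76 over 15 measured members, above all 10000 random lists, and 4 members were at least 2-fold higher: CCL2 (1.20), the apoptosis inhibitor BIRC3 (1.14), TNFAIP3 (1.05) and CXCL1 (1.03). TGF-beta and SMAD targets had a median of 0.33, also above all random lists, with COL1A1 (1.47), SMAD6 (1.19), COL7A1 (1.07) and ID3 (1.04). G1/S genes had a median of 0.17 (percentile 99.9), with CDK6 at 1.39, MCM3 at 0.73 and UNG at -1.02. G2/M genes were on the other side, with a median of -0.16 below all random lists, and 21 of 28 members were below 0, among them AURKB (-0.96) and CCNB1 (-0.46), while the spindle motor gene KIF11 was at 0.61.

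ATF4 amino acid response genes had a median of -0.18, below all random lists, with 19 of 24 members below 0, including the transporter gene SLC7A5 (-0.78) and CEBPG (-0.75). Cholesterol synthesis genes had a median of -0.16, again below all random lists, with MSMO1 at -0.95 and HMGCS1 at -0.54. Autophagy and lysosome genes had a median of -0.12 (percentile 0.090), with WIPI2 at -1.16 and ATG16L1 at -0.95. Fatty acid oxidation genes (median -0.13, percentile 0.54) included CPT1A at -0.66 and ETFA at -0.58. NRF2 antioxidant genes (-0.03, percentile 1.43) included HMOX1 at -0.86 and NQO1 at -0.85. Hypoxia genes (-0.10, percentile 0.76) included P4HA2 at -1.47 and DDIT4 at -0.65. Drug response genes had a median of 0.20 (percentile 99.3), with the deoxycytidylate deaminase gene DCTD at 0.91 and the nucleoside transporter gene SLC29A2 at 0.53. Of the pancreas and liver markers 4 were measured, with a median of 0.55 (percentile 98.5), SERPINA1 at 1.02 and APOA1 at 0.86.

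In total 12 of 33 ranked lists lay outside the central 95% of their random lists after FOXO3-siRNA, 5 above and 7 below, where 1.65 would be expected from random lists. The list shifts of hypoxia, fatty acid oxidation, NRF2 and drug response genes and of the 4 pancreas and liver markers did not stay outside under every alternative.

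FOXO target genes, the list closest to the silenced factor, had a median of 0.01 over 33 members (percentile 16.7). KLF2 (-1.06) and IRS2 (-0.93) were lower, and PMAIP1 (0.45) and TNFSF10 (0.45) higher. Of the FOXO factors only FOXO3 (-1.84) and FOXO1 (0.29) were measured, with a median of -0.78 and no rank.

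Metabolic lists near the center after FOXO3-siRNA were the pyruvate dehydrogenase complex (median -0.01; PDHX 0.95, DLAT 0.66, PDK2 -0.65), glycolysis (0.07; HK2 -0.70, SLC2A1 -0.46) and the TCA cycle (0.01; DLST -0.53, SUCLA2 -0.32). Oxidative phosphorylation subunits had a median of 0.08, with NDUFA8 at -1.94 and COX7B at -0.85 far from it. Fatty acid synthesis genes had a median of 0.01, with MLXIPL at 0.40 and ACSS2 at 0.15.

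Among the regulatory lists, endoplasmic reticulum chaperones had a median of -0.02 (PDIA4 -1.30, DNAJB9 -0.98), p53 targets 0.10 (TP53INP1 -1.54, BTG2 0.76) and apoptosis regulators 0.10 (BIRC3 1.14, XIAP -0.83). Interferon response genes had a median of 0.09 (XAF1 0.78, DDX60 -0.57) and insulin and growth factor signalling genes -0.06 (IGFBP1 -1.13, HBEGF -1.01). MYC targets had a median of 0.06 (MRTO4 -0.90, NOP58 0.27) and the siRNA machinery 0.11 (AGO4 -0.33, DICER1 0.31). Epithelial markers had a median of 0.09, with CDH1 at 1.46 from a dim signal and TJP1 at -1.19, and mesenchymal markers 0.13, with SNAI2 at 0.83 and TGFB2 at 0.51. Stem cell markers had a median of 0.00 (ABCG2 0.42, KLF4 -0.32).

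Ribosomal proteins had a median of 0.11, with RPS14 at 0.18 and RPL18 at 0.17, replication histones 0.00, with H2BC21 at 0.26 and H1-2 at 0.16, and housekeeping genes 0.05, with TBP at 0.40 and GUSB at -0.25. Few markers of other cell types were measured: 5 leukocyte markers had a median of -0.01 (CD14 0.42, CD68 -0.12), and 4 endothelial and fibroblast markers 0.10 (THY1 0.41, CDH5 0.22).

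**Figure D2:**
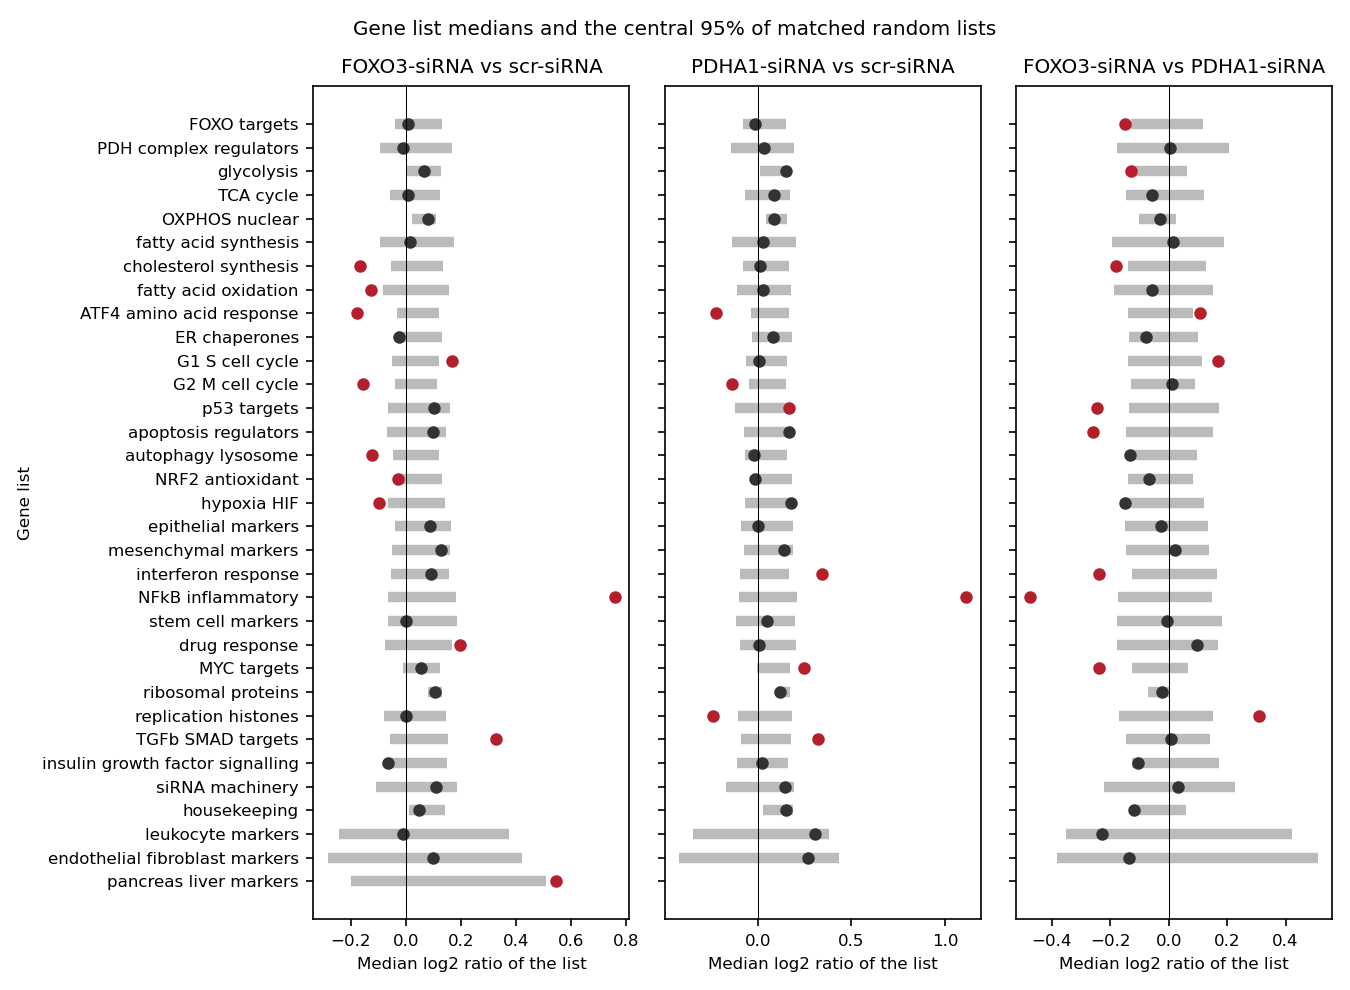
The median log2 ratio of each gene list is a point, red where it lies outside the central 95% of random lists matched on level, which is drawn as a grey bar, with 1 panel per comparison. NF-kB and inflammatory genes lay at 0.76 after FOXO3-siRNA, at 1.11 after PDHA1-siRNA and at -0.47 in the direct comparison.

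PDHA1-siRNA against scr-siRNA asked which transcripts differ when PDHA1, a subunit gene of the pyruvate dehydrogenase complex, is silenced. Inflammatory genes were among the highest: the chemokine gene CCL2 was 3.83-fold higher and the dendritic cell marker gene CD83 4.06-fold higher. The processed signal of BIRC3 was 21792 on the PDHA1-siRNA array against 6519 on the scr-siRNA array. EFHD2 was 4.08-fold higher. Below PDHA1, the branched-chain aminotransferase gene BCAT2 was 5.61-fold lower and the phosphatidylcholine transfer protein gene STARD7 was 5.35-fold lower.

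Among 16873 genes, 266 were at least 2-fold higher and 333 at least 2-fold lower after PDHA1-siRNA. At or above the median level, the highest were EFHD2 (log2 ratio 2.03), CD83 (2.02), BIRC3, CCL2 (1.94), MIGA1 (1.84) and the lipolysis inhibitor gene G0S2 (1.82). GNPNAT1 (1.78), which acts in hexosamine synthesis, MMP1 (1.78), TULP3 (1.75), CPOX (1.71), the Notch feedback gene NRARP (1.70) and EIF4EBP2 (1.70) followed. Among the lowest at that level, away from the local defects described next, were PDHA1 (-3.05), BCAT2 (-2.49), STARD7 (-2.42), the FGF receptor-like gene FGFRL1 (-2.19), CCNDBP1 (-2.17) and PRXL2B (3.99-fold lower). The other probe of CCNDBP1 gave 0.20.

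The ubiquitin ligase scaffold gene CUL5 (-3.28), the co-chaperone gene BAG3 (-3.20), PEMT (-2.25), EMP1 (-2.10) and the splicing factor gene SF3B2 (-2.07) were also among the 12 lowest, and each was read by 1 spot inside 1 of 2 streaks of low spots on the PDHA1-siRNA array. The limits of both streaks were set after the arrays were seen, so a raised share of low genes inside them was partly built in. In the streak within rows 1 to 60, 44 of 172 bright genes (25.6%) were at least 2-fold below their mean log2 level on the other arrays. In the streak at the left edge, within columns 1 to 32, 13 of 339 were (3.83%), against 168 of 8828 (1.90%) elsewhere.

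A further 562 genes were well above background on the PDHA1-siRNA array and not well above background on the scr-siRNA array, with a bound of at least 2-fold, and 90 genes showed the reverse. The guanylate cyclase gene GUCY1A1 was at least 15.6-fold higher, the glutaminase gene GLS2 at least 15.1-fold higher and FBXW10 at least 13.8-fold higher. Their spots lay in array rows 71, 28 and 19. In rows 1 to 200 of that array, 5.03% of the probes dim on both other arrays were well above background, against 0.321% in the remaining rows. At the lower end the largest bounds, for the apolipoprotein gene APOC1 (at least 45.6-fold lower), DIS3L (at least 39.9-fold) and PRKD2 (at least 27.7-fold), all came from spots inside the upper streak.

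**Figure D3:**
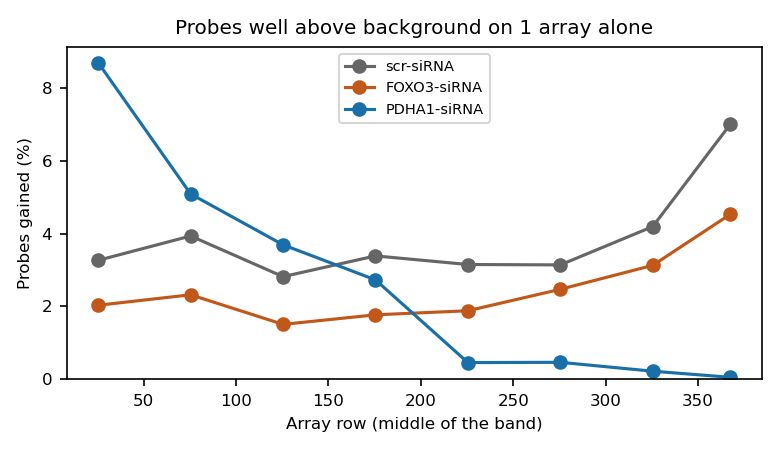
The share of probes dim on both other arrays that were well above background is plotted in percent by band of array rows, 1 line per array. On the PDHA1-siRNA array it was 8.69% in rows 1 to 50 and 0.0489% in the last band, where it was 7.01% on the scr-siRNA array and 4.53% on the FOXO3-siRNA array.

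NF-kB and inflammatory genes again stood furthest from matched random lists, with a median of 1.11 over 15 members and 12 of them at least 2-fold higher. NFKBIA, the inhibitor that NF-kB itself induces, was at 1.65 over 10 spots, and the chemokine gene CXCL8 was 2.82-fold higher from a dim signal. Interferon response genes had a median of 0.34, above all random lists, with 23 of 27 members above 0. With array rows 1 to 200 left out, their excess over matched genes went from 0.31 to 0.20 (percentile 98.95), still above the central 95%. The highest of them were dim or lay in those rows: IFNL1 (5.67-fold; row 64), IFI27 (1.79; row 5), XAF1 (1.42) and MX1 (1.28; row 28). TGF-beta and SMAD targets had a median of 0.32 (percentile 99.99), with ID3 at 1.03, JUNB at 1.03 and PMEPA1 at 0.82, while INHBA, spotted 10 times and partly inside the upper streak, was at -1.07. MYC targets had a median of 0.24 (percentile 99.99), including the nucleolar genes WDR43 (0.59), NOLC1 (0.57) and BOP1 (0.44). p53 targets had a median of 0.17 (percentile 97.8), with BTG2 at 1.22 and TP53INP1 at -0.90, and stayed outside the central 95% under 5 of 11 alternatives. With array rows 1 to 200 left out, the shifts of TGF-beta and MYC targets came back inside it.

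ATF4 amino acid response genes were lower in this knockdown too, with a median of -0.23 below all random lists, STC2 at -0.85, CHAC1 at -0.74 and GDF15 at -0.65. Replication histones had a median of -0.24 (percentile 0.050) with 15 of 15 members below 0, among them H2BC21 (-0.62), H3C2 (-0.57) and H4C8 (-1.79, inside the upper streak). G2/M genes had a median of -0.14 (percentile 0.050), with CENPF at -0.99 and KIF23 at -0.95, whereas KIF11 was at 0.73. In total 8 of 32 ranked lists lay outside the central 95%, 5 above and 3 below, where 1.60 would be expected from random lists.

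The lists nearest the pyruvate dehydrogenase reaction stayed inside it. The pyruvate dehydrogenase complex and its regulators had a median of 0.03, with the subunit genes DLAT at 0.93 and PDHX at 0.90 and the kinase gene PDK4 at -0.78. Glycolysis genes had a median of 0.15 (percentile 89.7), with ALDOC at 0.79, LDHA at 0.36 and the lactate transporter gene SLC16A1 at -0.69. TCA cycle genes had a median of 0.09, with IDH2 at -0.97 and OGDH at -0.54. Oxidative phosphorylation subunits had a median of 0.08, with UQCRC2 at -0.95. Fatty acid oxidation genes had a median of 0.03, with ETFA at -1.75, and hypoxia genes 0.17 (percentile 97.3), with ANGPTL4 at 1.55 and ADM at 0.74. Within FOXO target genes (median -0.02), TXNIP, a brake on glucose uptake, was at -1.35.

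Other large single values were ITGA5 (-2.10), CLDN1 (1.58), ELF3 (-1.32), KLF4 (-1.30), DCTD (1.18) and PCNA (-1.13). Ribosomal proteins had a median of 0.12, and the one far from it, RPS6 (-1.21), was read by a spot in the upper streak, while its other probe gave 0.26. Of the growth factor signalling genes (median 0.02), IGFBP1 was at -1.39 and the ERK phosphatase gene DUSP6 at 1.17.

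**Figure D4:**
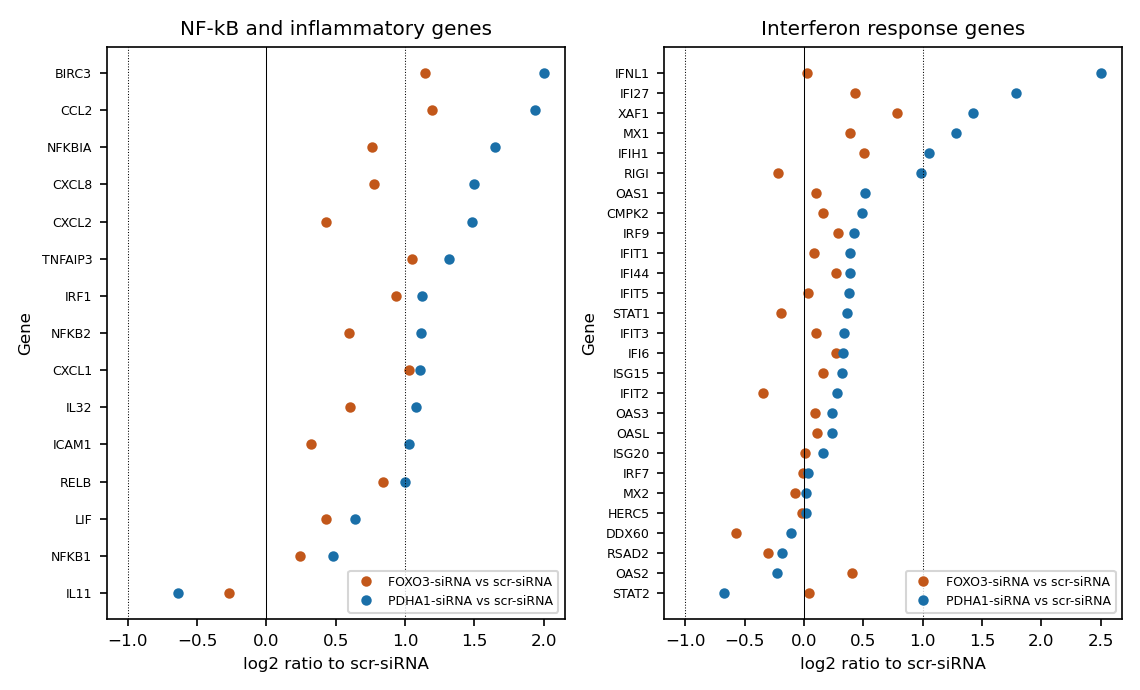
The log2 ratio to scr-siRNA is plotted for each measured NF-kB and inflammatory gene and interferon response gene, with 1 point per knockdown and dotted lines at 2-fold. In the NF-kB panel 12 of 15 genes were at least 2-fold higher after PDHA1-siRNA and 4 of 15 after FOXO3-siRNA.

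FOXO3-siRNA against PDHA1-siRNA compared both knockdowns without the control array. PDHA1 was 8.61-fold higher and FOXO3 (log2 ratio -1.74) lower after FOXO3-siRNA. The FOXO3 spot used lay inside the left-edge streak of the PDHA1-siRNA array, and the other FOXO3 probes gave -1.73 and -1.52. BZW1 was 7.71-fold lower after FOXO3-siRNA than after PDHA1-siRNA, with its other probes at -2.91 and -1.62. NF-kB genes were lower, and replication histones and G1/S genes higher, after FOXO3-siRNA.

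Among 16787 genes, 399 were at least 2-fold higher and 327 at least 2-fold lower after FOXO3-siRNA than after PDHA1-siRNA. The balance depended on the setting, with 332 higher and 321 lower with the 2 streaks left out, and 1590 and 2084 without a filter on dim probes. At or above the median level, the highest were CUL5 (3.17), PDHA1 (3.11), STARD7 (2.68), BCAT2 (2.57), PRXL2B (2.40) and PEMT (2.36), of which CUL5 and PEMT lay in the streaks. The lowest at that level were BZW1 (-2.95), PPP1R2 (-2.49), the hexosamine gene UAP1 (-2.40), TENT5C (-2.38), PCNP (-2.36) and the metallothionein gene MT1M (-2.13). A further 142 genes were not well above background on the PDHA1-siRNA array, with APOC1 at least 51.1-fold, DIS3L at least 49.4-fold and RTKN at least 27.7-fold higher after FOXO3-siRNA, all from spots in the upper streak. For 533 genes it was the reverse, with GUCY1A1 at least 13.6-fold, GRB7 at least 13.3-fold and GLS2 at least 13.2-fold lower, all from rows 1 to 200.

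NF-kB and inflammatory genes had a median of -0.47, below all random lists, with CXCL2 at -1.05 and NFKBIA at -0.89. MYC targets had a median of -0.24, also below all random lists, with MRTO4 at -1.12 and WDR43 at -0.67. Interferon response genes (-0.24, percentile 0.060) had RIGI at -1.21, and p53 targets (-0.24, percentile 0.070) had SESN2 at -0.65 and BAX at -0.64. Apoptosis regulators (-0.26, percentile 0.080) had XIAP at -0.98 and the caspase gene CASP8 at -0.93. Cholesterol synthesis genes (-0.18, percentile 0.63) had HMGCS1 at -1.30 and SC5D at 0.88. FOXO target genes had a median of -0.15 (percentile 1.07), with IRS2 at -0.93 and TXNIP at 1.36, and glycolysis genes -0.13 (percentile 1.62), with HK2 at -0.73 and PFKP at -0.31.

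On the other side, replication histones had a median of 0.31 (percentile 99.95; H2BC21 0.88, H1-2 0.64), G1/S genes 0.17 (percentile 99.6; CDK6 1.78, PCNA 1.30) and ATF4 amino acid response genes 0.11 (percentile 99.1; STC2 0.65, MTHFD2 -0.85). For ATF4 genes, 13 of 24 members were above 0, and the shift came back inside the central 95% with the mean of the probes. In total 11 of 32 ranked lists lay outside the central 95%, 3 above and 8 below, where 1.60 would be expected from random lists. With array rows 1 to 200 left out, the shifts of p53, apoptosis, interferon, MYC, cholesterol, glycolysis and FOXO target genes came back inside it. Glycolysis genes also did so under quantile normalization, with the authors' value table and without the filter on dim probes, FOXO target genes under normexp and without that filter, and cholesterol genes without that filter.

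Among genes at or above the median level, both knockdowns had several far from scr-siRNA in the same direction. EFHD2 (1.78 after FOXO3-siRNA and 2.03 after PDHA1-siRNA), MIGA1 (1.78 and 1.84), EIF4EBP2 (1.90 and 1.70), CPOX (1.65 and 1.71) and AKIRIN1 (1.60 and 1.66) were the 5 highest in both. IGFBP1 (-1.13 and -1.39), the secreted insulin-like growth factor binding protein gene, LMO4 (-1.33 and -1.10), RAB31 (-1.87 and -1.09), SNX4 (-1.20 and -1.07) and the SUMO protease gene SENP5 (-1.03 and -1.30) were the 5 lowest in both.

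Across 16742 genes well above background on all 3 arrays, Pearson's r of the ratios was 0.323. Simulations that shuffled each gene's values among the arrays gave a mean of 0.4999 (lowest to highest of 100 simulations 0.468 to 0.535). The covariance was 0.0469 against a simulated 0.0833, a difference of -0.0364. At 2-fold, 62 genes were higher in both against a simulated 152 and 1.92 for independent counts, and 17 were lower in both against a simulated 37.2 and 4.34. Genes are not independent replicates. The r and both overlaps were below the simulated values. The shuffled values keep the knockdown differences and local array defects in their spread, so they do not show what a shared control alone gives. Whether the knockdowns share effects therefore cannot be told from these values.

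**Figure D5:**
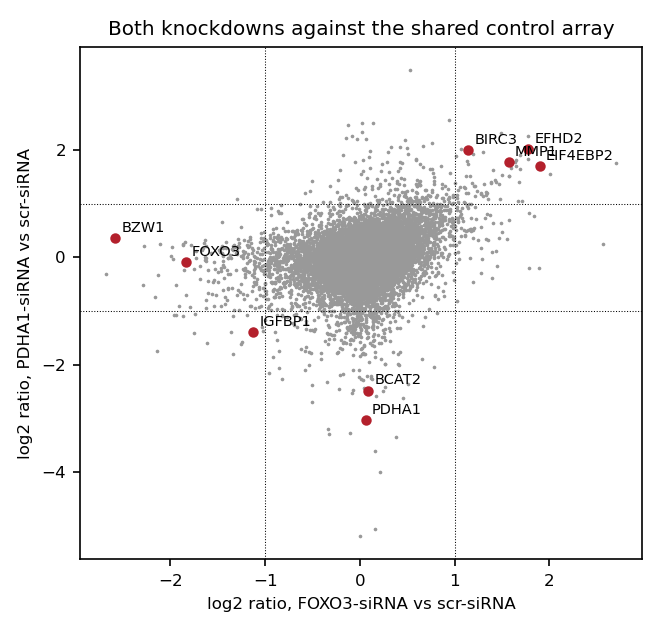
Each point is 1 gene, with its log2 ratio to scr-siRNA after FOXO3-siRNA on the horizontal axis and after PDHA1-siRNA on the vertical axis, and dotted lines at 2-fold. EFHD2, at 1.78 and 2.03, and EIF4EBP2, at 1.90 and 1.70, lie far out in both, whereas BZW1, at -2.58 on the horizontal axis, and BCAT2, at -2.49 on the vertical axis, stand out in 1 knockdown each.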

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

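The tests of bright NF-kB members and of other probes of lowered genes were set before their results were seen, whereas every test that uses array rows, the streaks, the direct comparison or the control array in this part was chosen after the result was seen.

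A second probe of PDHA1, on chromosome X at 19371381 to 19371440 and outside the comparisons, was well above background on the PDHA1-siRNA array alone. Its processed signal was 65.6 there against 4.45 on the scr-siRNA array and 6.48 on the FOXO3-siRNA array, while the brighter PDHA1 probe read 998 against 9869 and 9129. The spot lies in array row 21, within the rows where most probes well above background on that array alone lay. A spot of BCKDHB, a branched-chain keto acid dehydrogenase subunit gene, was left out because the scanner software marked it as uneven. It read 441994 on the FOXO3-siRNA array against 701 on the scr-siRNA array and 577 on the PDHA1-siRNA array, 630-fold the larger of the other signals. The left-out value came from 1 spot of that array.

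The NF-kB and inflammatory genes stood above matched genes on both knockdown arrays, with BIRC3, CCL2 and TNFAIP3 at least 2-fold higher on each. A raised signal in rows 1 to 200 of the PDHA1-siRNA array is argued against, since the excess over matched genes was 1.06 with these rows left out and 1.05 with them. Scatter of dim probes is argued against too, as the members at or above the median level had an excess of 1.01. A low reading of these genes in the 1 control culture would raise both knockdown arrays alike, and it is argued against as the whole of the PDHA1-siRNA excess, because the direct comparison, which does not use the control, gave an excess of -0.46 with 14 of 15 members below 0. For the excess of 0.70 after FOXO3-siRNA, and for as much of the PDHA1-siRNA excess, a low control and an effect of the knockdowns cannot be told apart. Whether the gap between the knockdown arrays came from the knockdowns or from the single cultures was not tested. An inflammatory response to either siRNA itself, rather than to loss of its target, likewise stays open and untested.

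On each knockdown array more genes stood alone on the low side than on the high side: 128 genes were at least 2-fold lower than on both other arrays after FOXO3-siRNA and 20 were higher, and after PDHA1-siRNA the counts were 261 and 75. On the scr-siRNA array they were 62 and 17. Single defective spots are argued against as the source of all lowered genes on the FOXO3-siRNA array. There, 67.9% of the other probes of the lowered genes (36 of 53, exact 95% interval 53.7 to 80.1) were at least 0.5 log2 units lower too. BZW1 and PPP1R2 were among them, and for other genes the share was 3.76%. For the PDHA1-siRNA array the share was 48.1% (51 of 106, 38.3 to 58.0), and 56.4% outside the streaks (44 of 78, 44.7 to 67.6). For other genes the shares on that array were 6.53% and 5.59%, so its lowered genes were also low by their other probes far more often than other genes. Both PDHA1-siRNA intervals include 50%, the limit used, so the comparison did not decide for that array. On either knockdown array, defective spots may account for part of the lowered genes. The 53, 106 and 78 probes came from 41, 84 and 62 genes, and the intervals treat probes as independent. They are thus too narrow, and whether the FOXO3-siRNA interval would still exclude 50% was not tested. With the 2 streaks left out, lowered genes on the PDHA1-siRNA array were still 2.66 times as many as raised ones (202 against 76). The same ratio was 3.59 on the scr-siRNA array and 6.58 on the FOXO3-siRNA array. More lowered than raised genes thus remained without the streaks, but this was not particular to the PDHA1-siRNA array or to a knockdown. With rows 1 to 200 left out, 126 genes were lower and 14 higher on the PDHA1-siRNA array, against 25 and 12 on the scr-siRNA array. The upper streak lies within those rows and is left out under that setting, whereas the left-edge streak lies beyond row 200 and stays in. More lowered than raised genes thus remained on the PDHA1-siRNA array without the upper streak. These counts do not bear on the left-edge streak. Whether array position shaped these counts was not tested. Silencing of unintended transcripts by each siRNA is a biological candidate explanation that stays open, because neither the siRNA sequences nor the 3′ untranslated regions were analysed here.

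Probes well above background on the PDHA1-siRNA array alone, such as those of GUCY1A1, GLS2 and FBXW10, lay mostly in its first rows. The share was 5.03% in rows 1 to 200 and 0.321% beyond them, against 3.35% and 4.12% on the scr-siRNA array and 1.90% and 2.85% on the FOXO3-siRNA array. Transcripts present only after PDHA1-siRNA, without any effect of array position, are argued against by the 0.321%, because probe positions are unrelated to gene function. The 0.321% was also below the 4.12% and 2.85% of the other arrays beyond row 200, which argues against a rise of the signal in rows 1 to 200 alone. In rows 1 to 200 the share was 1.502 times the larger of those on the other arrays. Whether a rise in these rows came on top of a loss of dim signal beyond them cannot be told. Whether GLS2 or any other single gene among them was also higher in the cells was not tested.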

How the results depend on the processing

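The 75th percentile over all probes, keeping the marked spots, leaving out array rows 1 to 200 and leaving out the 2 streaks were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because each group has 1 array and the labels link no cultures. Of 42 main results (gene counts, target levels, the relation of the knockdowns and the lists outside the central 95%), all 42 kept their direction and size under median centring, the percentile over all probes and the kept spots, and 41 of 42 did under quantile normalization and under the authors' table. Median centring and the percentile over all probes only subtract another constant from each array. Apart from the random draws, list excesses and Pearson's r could not change under them, so these tallies are no independent check. The tally was 40 of 42 with the mean of the probes and also with the streaks left out. It was 32 of 42 without the filter on dim probes, 32 of 41 under the stricter filter, 24 of 42 under normexp and 19 of 40 with rows 1 to 200 left out. Leaving out every probe with a marked spot was run for the 6 gene counts, which stayed within 1.5 times. The FOXO3 ratio ranged from -1.87 to -1.76 over 11 alternatives, and Pearson's r from 0.281 to 0.410. The PDHA1 ratio ranged from -3.08 to -2.93 over 9 alternatives. With rows 1 to 200 left out PDHA1 had no value, as its probe lies there. NF-kB genes stayed outside the central 95% in all 3 comparisons under 11 of 11 alternatives, as did ATF4 and G2/M genes in both knockdowns against scr-siRNA. The 11 include median centring and the percentile over all probes, which could not move them. Unless stated, the cause of a difference was not tested.

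Averaging the probes gave 0.55 for PDHA1 after PDHA1-siRNA and -0.16 in the direct comparison, both reversed by its dim probe, and an excess of 0.33 for TGF-beta targets after FOXO3-siRNA. The NF-kB excess after FOXO3-siRNA was 0.62 under quantile normalization and 0.63 from the authors' table.

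Under normexp, whose offset shrinks ratios of dim genes by construction, the counts higher and lower were 59 and 129 after FOXO3-siRNA, 133 and 211 after PDHA1-siRNA, and 238 and 180 in the direct comparison, with 34 genes higher and 9 lower in both knockdowns. PDHA1 was at -2.93. List excesses after FOXO3-siRNA were -0.092 for fatty acid oxidation, -0.075 for hypoxia, 0.50 for NF-kB, 0.22 for TGF-beta and 0.10 for pancreas and liver genes. The NF-kB excess after PDHA1-siRNA was 0.90, and in the direct comparison p53 targets had -0.16, apoptosis regulators -0.17 and interferon genes -0.18.

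Without a filter on dim probes more genes were counted: 1831 higher and 1110 lower after FOXO3-siRNA, 2360 and 1166 after PDHA1-siRNA, 1590 and 2084 in the direct comparison, and 455 higher and 350 lower in both knockdowns. Pancreas and liver genes had an excess of 0.15 after FOXO3-siRNA, and NF-kB genes -0.36 in the direct comparison. The stricter filter, with fewer genes, left 50 higher and 132 lower, 75 and 194, and 210 and 162 in the same order, and 32 higher and 7 lower in both, and p53 targets had -0.40 in the direct comparison. Signal over background thus limits the counts, and without the filter the balance of higher and lower genes turned in each comparison.

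With rows 1 to 200 left out, which left 9962, 9448 and 9410 genes in the 3 comparisons, the counts were 79 and 137, 94 and 173, and 205 and 142, with 25 genes higher in both. After FOXO3-siRNA the excesses were -0.27 for ATF4, -0.045 for hypoxia and 0.37 for TGF-beta genes. After PDHA1-siRNA they were -0.47 for ATF4, 0.20 for interferon, 0.094 for MYC, -0.38 for histone and 0.18 for TGF-beta genes. In the direct comparison they were -0.052 for FOXO targets, -0.057 for cholesterol, -0.067 for p53, -0.11 for apoptosis, -0.16 for interferon and -0.095 for MYC genes. RPS6 after PDHA1-siRNA was reversed to 0.24. With the streaks left out the counts were 147 and 217, 260 and 271, and 332 and 321 in the same order. RPS6 was then at 0.25, hypoxia genes after FOXO3-siRNA at -0.040 and apoptosis regulators in the direct comparison at -0.39. In both cases RPS6 was then read by its other probe.

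Of 4714 values of named genes under the alternatives, 4313 stayed within the spread of repeated spots, 397 moved by more, and 4 were counted as reversed. Part of this was fixed in advance. Without the filter on dim probes the ratios came from the same probe values (447 of 447 unmoved). Median centring and the percentile over all probes shift all ratios of a comparison alike (465 of 465 unmoved under each). Those 4 were of PDHA1 and RPS6. Reversal was counted only for bounds and for ratios of at least 2-fold in the main setting, so sign changes of smaller ratios were not counted.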

Other observations

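The gene families in this part were screened after the data were seen, as symbols of protein-coding genes that share the same leading letters and have at least 6 measured members. They were ranked by their excess over matched genes divided by the SD of the random list medians. Of 332 families after FOXO3-siRNA, 40 lay outside the central 95% of matched random lists where 16.6 would be expected, and after PDHA1-siRNA it was 36 of 320 where 16.0 would be expected.

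Intraflagellar transport genes (IFT), which build the primary cilium, ranked lowest of the 332 families after FOXO3-siRNA. Their median log2 ratio was -0.42 and 13 of 16 members were below 0, with IFT56 at -0.75, IFT88 at -0.70 and IFT81 at -0.62. Their excess over matched genes ranged from -0.48 to -0.16 over the settings run. Under the stricter brightness filter the 8 brighter members had a median of -0.13 (percentile 3.40), inside the central 95%. After PDHA1-siRNA the IFT median was -0.20, with IFT88 at -1.26, and it went to 0.01 under 1 setting. Dynein arm assembly factors (DNAAF), which serve motile cilia, had a median of -0.31 after FOXO3-siRNA with 7 of 7 members below 0, but the 4 members kept by the stricter filter lay inside the central 95% (percentile 7.80). Genes named for cilia and flagella (CFAP) ranked 3 from the lowest after FOXO3-siRNA with a median of -0.27, but only 9 of 16 members were below 0. Under the stricter filter the 8 brighter CFAP members had a median of 0.003 (percentile 31.65), so the shift was not seen in them.

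Subunits of the CCT chaperonin, which folds actin and tubulin, were lower after FOXO3-siRNA than after PDHA1-siRNA. Their median was -0.20 after FOXO3-siRNA, with CCT6A at -0.42 and CCT4 at -0.30, and 0.21 after PDHA1-siRNA, with CCT2 at 0.39 and CCT6A at 0.24. The PDHA1-siRNA value was inside the central 95% (percentile 95.6). The FOXO3-siRNA median was -0.068 under normexp, still below the central 95%, and -0.074 with array rows 1 to 200 left out, inside it (percentile 2.53). In the direct comparison 7 of 7 CCT genes were below 0, with a median of -0.45, and the median ranged from -0.48 to -0.33 over the settings run.

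Metallothionein genes (MT) ranked highest of 320 families after PDHA1-siRNA, with a median of 0.41 and 8 of 9 members above 0, including MT1X at 0.48 and MT1E at 0.41. The metallothionein sequences are similar, so their probes can share signal. After FOXO3-siRNA the MT median was 0.05 and MT1M stood apart at -1.84. HLA genes had a median of 0.39 after PDHA1-siRNA with 8 of 9 members above 0, led by HLA-B (0.48) and HLA-C (0.45), and a median of 0.09 after FOXO3-siRNA. By excess over matched genes alone, HLA genes (0.30) lay slightly above MT genes (0.29) after PDHA1-siRNA. Without the filter on dim probes the HLA excess after PDHA1-siRNA went from 0.30 to 0.15, inside the central 95% (percentile 89.1).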
